A study of Homo sapiens with 9 samples.

How the data were processed

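The series holds 9 RNA sequencing libraries of CFF-16HBEge cells, 3 from plasmid lipofection, 3 from eVLP transduction and 3 controls, which were untreated, mock-transduced and mock-transfected cells, 1 library each. According to the labels, total RNA was isolated with a Monarch Total RNA Miniprep kit, mRNA was enriched on oligo(dT) beads, and strand-specific libraries were made with the NEBNext Ultra II Directional kit. The submitters' notes name bcl2fastq 2.20, Trimmomatic 0.36, STAR 2.5.2b, Subread 1.5.2 and featureCounts and the genome build GRCh38; the strand setting and the annotation release used for counting are not given in the sources used here. The authors deposited raw counts for 57500 genes with Ensembl identifiers, which were whole numbers. The authors' deposited tables of comparisons give log2 fold changes, p-values and adjusted p-values, with per-library signal columns that equal the raw counts times 1 factor per library and table, for genes with more than 60 counts over the 6 libraries compared. The authors' deposited Gene Ontology tables give p-values and numbers of genes per term, and the tools behind these tables are not given in the sources used here. The authors' plasmid against control table left 1330 genes without an adjusted p. Across genes, its log2 values and those computed here correlated at 0.9998, and those of the other 2 tables at 0.9997 and 0.9999.

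Libraries held 24398095 to 48843422 counts, so 3 counts, taken as the floor, came to 0.0614 to 0.123 CPM per library. Counting intervals are exact 95% intervals, and both they and floors cover counting error only, since reads carry no molecular identifiers. No pair of libraries of a group differed by as little as sampling noise, so each was counted as 1 replicate. Among genes with at least 50 counts, chi-square over degrees of freedom was 50.0 to 87.3 for control, 10.2 to 34.0 for eVLP and 16.5 to 24.3 for plasmid pairs. Whether the replicates came from separate cultures is not stated in the labels, so p-values measure only the spread between these samples, which may be technical. In the control group this spread includes differences between untreated and mock-treated cells. Control pairs lay furthest apart, while the fit takes the same spread for all groups, which may favour calls against control.

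Gene symbols were checked against GENCODE release 29, which matched 56410 genes; 27 symbols that had turned into dates were restored, and 485 genes had no symbol. The same annotation gave the coordinates on GRCh38. Counts were analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr by group kept 17984 genes with 99.92% of counts, TMM gave the scaling, and 1 quasi-likelihood fit of all 9 libraries gave the 3 comparisons (common biological coefficient of variation 0.149, 6 residual and 4.42 prior degrees of freedom). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and counts at an absolute log2 change of at least 1 are given as well. CPM are scaled by TMM without a prior count, and fold changes are those of the fit. The groups, comparisons, tests, gene lists, rule for named genes and the alternatives not said to be added later were chosen before the data were examined.

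Gene lists numbered 30, with 560 genes of which 559 were found: interferon-stimulated genes, interferons and chemokines, nucleic acid sensing, NF-kB and cytokines, MHC class I antigen presentation, p53 targets, ATF4, unfolded protein response, cytosolic heat shock, NRF2, cholesterol synthesis, fatty acid synthesis, lysosome, mitosis, DNA replication, base excision and mismatch repair, immediate early response, TGF-beta and matrix, hypoxia and glycolysis, nonsense-mediated decay, airway ion transport, keratins and junctions, secretory, ciliated and ionocyte markers, squamous differentiation, fibroblast, leukocyte and HEK293 markers, mitochondrial mRNAs, histones and ribosomal proteins. Each list was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the 30 lists of a comparison, and again with an estimated correlation, which kept 0, 2 and 2 of the 10, 14 and 13 calls. The genes named are CFTR, the 6 highest and 6 lowest changes per comparison among called genes with a mean of at least 2 CPM and no overlap between groups, 4 members of each called list or list with at least 3 called members, and up to 2 of the others; named exceptions are marked as chosen after their values were seen, and 2 genes that the rule singles out are not reported here. Further lists for the closing section were non-ribosomal mRNAs with a terminal oligopyrimidine tract, snoRNA host transcripts, liver X receptor targets, 7SL RNA genes and 7 other small RNA genes of RNA polymerase III, of which 0 were measured. Their members not already in the 30 lists were chosen before their values were seen, except the 7SL RNA genes. The liver X receptor list shares SREBF1 and SCD with the fatty acid list, so these cannot be counted as unseen.

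Replicate numbers were checked for pairing by correlating deviations from the group means. Same-numbered plasmid and eVLP libraries correlated at 0.17, 0.27 and 0.24, each over 0.1, so the numbers were taken to pair these libraries, from the data and not from the labels. Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, robust estimation, no filter, a filter of 10 counts in 3 libraries, a fit of only the 6 libraries, the replicate number as a block, leaving out each library, and each treatment's own mock library or both mock libraries as the control. Offsets for GC content and gene length, and the replicate block with these offsets or in only the 6 libraries, were added after the data had been seen. The procedure was tested on simulated data: with changes of 1.5, 2 and 4-fold among 17054 genes, 37.3, 73.1 and 95.5% of changed genes were recovered for plasmid against control, 35.8, 73.1 and 93.9% for eVLP against control and 45.5, 76.1 and 97.7% for plasmid against eVLP, with 9 of 155, 13 of 164 and 23 of 337 false calls. The changed genes were drawn above a minimum mean count and outside the gene lists, and were fewer than those called in the real data. All simulated groups had the same spread and no pairing, so these shares may not hold for the real comparisons. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.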

Results

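Gene expression was measured by RNA sequencing in CFF-16HBEge cells, a gene-edited human bronchial epithelial line that is homozygous for the nonsense variant G542X of CFTR, the chloride channel gene mutated in cystic fibrosis. All 9 libraries were made from cells collected about 48 h after treatment. In 3 of them base editing reagents had been delivered as plasmid DNA by lipofection, and in 3 by engineered virus-like particles (eVLPs), retrovirus-derived particles that carry protein cargo into cells. The control group held 1 untreated, 1 mock-transduced and 1 mock-transfected library. Libraries held 31514864 to 48843422 counts in the control group, 24398095 to 35819563 in the eVLP group and 33757844 to 38033149 in the plasmid group. Levels are CPM (counts divided by normalised library size, per 1e6), mean ± SD over 3 libraries per group, and p-values are from the edgeR fit of 17984 genes. The first 3 principal components held 39.4%, 22.0% and 14.1% of the variance. On the first, the eVLP libraries lay between 40.2 and 58.0 and the plasmid libraries between -46.0 and -28.1, with the control libraries between -25.8 and -2.96.

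CFTR (ENSG00000001626, GRCh38 chromosome 7, 117465784 to 117715971, protein-coding) was measured at 136 ± 21.7 CPM in control, 137 ± 7.42 CPM in eVLP and 176 ± 9.98 CPM in plasmid libraries. Codon 542, which G542X turns into a stop codon, lies at 117587778 to 117587780 in exon 12 of 27 of the transcript that sets the numbering. Gene counts do not show which base stands there, so editing was not measured here. CFTR rose by a log2 of 0.37 (SE 0.11) from eVLP to plasmid libraries, with adjusted p = 0.0306. This call was lost whichever of the 6 libraries was left out, with values of 0.33 to 0.41 and adjusted p of 0.0529 to 0.109, and with upper-quartile scaling (0.30, adjusted p = 0.0540). It was kept with the replicate number as a block (adjusted p = 0.0217), in only the 6 libraries (0.00498), with both (0.000496, a setting added after the data had been seen) and by DESeq2 (0.0134). From control to plasmid libraries the value was also 0.37 (adjusted p = 0.0564, and 0.0093 to 0.194 over the alternative settings), and from control to eVLP libraries it was 0.00 (adjusted p = 0.984).

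The comparison of plasmid with control libraries asks how lipofection of editor plasmids changed the cells. HSPA6 (ENSG00000173110, GRCh38 chromosome 1, 161524540 to 161526910), a strictly inducible member of the HSP70 chaperone family, rose 314-fold, from 1.73 ± 0.391 to 539 ± 49 CPM (adjusted p = 2.50e-08). Of 13 measured genes of the cytosolic heat shock list, 11 rose, 0 fell and 2 did not pass the test (12 and 0 adjusted over the list alone). Heat shock genes had a median log2 change of 0.62 and a camera adjusted p = 2.06e-20, adjusted p = 0.0557 with an estimated correlation. BAG3 (ENSG00000151929, GRCh38 chromosome 10, 119651370 to 119677819), a co-chaperone of HSP70, rose 2.71-fold, 156 ± 17.9 against 57.7 ± 11.3 CPM, adjusted p = 0.00219. The stress-inducible HSP70 genes HSPA1B and HSPA1A rose 3.29-fold (762 ± 66.3 against 232 ± 57.7 CPM) and 3.14-fold (574 ± 70.2 against 183 ± 50.7 CPM), and DNAJB1, the HSP40 partner of HSP70, rose 1.66-fold, 541 ± 49.6 against 326 ± 18 CPM, adjusted p = 0.00558. HSPA1A and HSPA1B have nearly the same sequence, so their counts can share reads. HSPA7, a pseudogene close to HSPA6 in sequence that was chosen after its values were seen, stood at 3.16 ± 0.601 CPM in plasmid and 0.0359 CPM in control libraries.

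Other genes with large changes included KLKP1, a kallikrein pseudogene, which rose 45-fold, 5.54 ± 1.07 against 0.125 ± 0.0418 CPM, adjusted p = 0.00179. ADAM19, a membrane-anchored metalloprotease, rose 6.87-fold, 147 ± 65.7 against 21.5 ± 7.53 CPM, adjusted p = 0.0111, and the pseudogene AC083899.2 rose 6.99-fold, 4.32 ± 1.18 against 0.614 ± 0.298 CPM, adjusted p = 0.0111. KRT33B, a hair keratin, and KRTAP2-3, a keratin-associated protein, rose 11.4-fold (7.97 ± 1.95 against 0.723 ± 0.541 CPM) and 8.56-fold (8.51 ± 4.86 against 0.998 ± 0.50 CPM). The largest falls were those of the pseudogenes TMSB4XP4 and AL591846.1, at log2 changes of -2.17 and -2.17. AQP3, a water and glycerol channel of epithelia, fell (log2 change -2.0, 27.9 ± 8.75 against 112 ± 52.9 CPM, adjusted p = 0.0252), as did ALPP, an alkaline phosphatase, at -1.95, the interferon-induced GTPase GBP2 at -1.94 and the pseudogene HLA-J at -1.90. Counts of keratins, pseudogenes and HLA genes can include reads of related sequences. Of the genes in this paragraph, KRT33B, KRTAP2-3, TMSB4XP4, AQP3, ALPP, GBP2 and HLA-J were no longer called without plasmid replicate 1, without plasmid replicate 3 or without control replicate 1, ALPP and GBP2 also without plasmid replicate 2 and GBP2 without control replicate 2.

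The list of mitochondrially encoded mRNAs was called upward in plasmid libraries at the preset correlation. Among 13 measured members, 9 rose, 1 fell and 3 did not pass the test (10 and 1 adjusted over the list alone). Mitochondrial mRNAs had a median log2 change of 0.64 and a camera adjusted p = 4.03e-15, adjusted p = 0.226 with an estimated correlation. MT-ATP6, a subunit of ATP synthase, rose 1.83-fold, 1606 ± 47.5 against 877 ± 65.1 CPM, adjusted p = 0.00179, and MT-ND2, a complex I subunit, rose 1.84-fold. MT-CO1, of complex IV, rose 1.77-fold and MT-CYB, of complex III, 1.64-fold, the last of which was not called without plasmid replicate 1. The member that fell was MT-ND3 (log2 change -0.55, adjusted p = 0.0410), chosen after its values were seen. Mitochondrial genes took 1.54 ± 0.0304% of all counts in plasmid and 0.994 ± 0.0888% in control libraries.

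In the endoplasmic reticulum (ER), the unfolded protein response list had 20 measured genes, of which 5 rose, 0 fell and 15 did not pass the test (10 and 2 adjusted over the list alone). Unfolded protein response genes had a median log2 change of 0.27 and a camera adjusted p = 0.000132, adjusted p = 0.662 with an estimated correlation. SDF2L1, an ER stress-inducible chaperone cofactor, rose 1.63-fold, PDIA4, a protein disulfide isomerase, 1.42-fold, HSP90B1, the ER HSP90, 1.43-fold, and HSPA5, the ER HSP70 also called BiP, 1.31-fold (1823 ± 76.7 against 1392 ± 124 CPM). Of 14 genes of fatty acid synthesis and lipid storage, 1 rose, 0 fell and 13 did not pass the test (1 and 0 adjusted over the list alone). Fatty acid genes had a median log2 change of 0.25 and a camera adjusted p = 0.037, adjusted p = 0.662 with an estimated correlation. The 1 that rose was FASN, fatty acid synthase, at 1.53-fold. No hypoxia and glycolysis gene passed the test over all genes: of 17 members 0 rose, 0 fell and 17 did not pass the test (4 and 0 adjusted over the list alone). Hypoxia and glycolysis genes had a median log2 change of 0.16 and a camera adjusted p = 0.037, adjusted p = 0.662 with an estimated correlation. ENO1, an enolase, stood at 1394 ± 155 against 1104 ± 99.7 CPM. The calls of these 5 genes were lost without plasmid replicate 1, plasmid replicate 3 or control replicate 1, and those of HSPA5 and FASN also without plasmid replicate 2 or control replicate 3. The fatty acid list was not called without plasmid replicate 1 or 2 or control replicate 1 or 3, the hypoxia list not without plasmid replicate 1 or 3 or control replicate 1 or 3, and neither against both mock libraries.

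Called downward in plasmid libraries, at the preset correlation only, were the lists of antigen presentation, interferon-stimulated and nucleic acid sensing genes, although few of their members passed the test. Of 17 MHC class I antigen presentation genes, 0 rose, 3 fell and 14 did not pass the test (0 and 9 adjusted over the list alone). Antigen presentation genes had a median log2 change of -0.52 and a camera adjusted p = 6.20e-07, adjusted p = 0.662 with an estimated correlation. The proteasome activator PSME2 fell by 0.60 on the log2 scale (184 ± 11.9 against 279 ± 45.2 CPM), the peptide transporter TAP1 by 0.50 and the immunoproteasome subunit PSMB9 by 0.90. Of 40 interferon-stimulated genes, 0 rose, 2 fell and 38 did not pass the test (0 and 1 adjusted over the list alone). Interferon-stimulated genes had a median log2 change of -0.36 and a camera adjusted p = 9.91e-05, adjusted p = 0.713 with an estimated correlation. IFI35 and DTX3L, both interferon-induced, fell (-0.74 and -0.46). Of 16 nucleic acid sensing genes, 0 rose, 2 fell and 14 did not pass the test (0 and 3 adjusted over the list alone). Nucleic acid sensing genes had a median log2 change of -0.24 and a camera adjusted p = 0.0193, adjusted p = 0.662 with an estimated correlation. SAMHD1, a nucleotide hydrolase that restricts viruses, fell (-0.50), as did IFIH1, the RNA sensor MDA5 (-0.54). Each gene call in this paragraph was lost without plasmid replicate 1, without plasmid replicate 3 or without control replicate 1, those of TAP1, DTX3L and IFIH1 also without control replicate 2 and that of DTX3L without plasmid replicate 2. Against the mock-transfected library alone none of these 3 lists was called, and the median of the interferon-stimulated genes was 0.045. The mock-transfected library is control replicate 3, the best match of plasmid replicate 3, so mock treatment and replicate number cannot be told apart there. Without control replicate 2 the interferon and nucleic acid sensing lists were not called, and without plasmid replicate 3 the nucleic acid sensing list was not.

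The ribosomal protein and mitosis lists were called downward at the preset correlation only, with few members past the test. Of 24 ribosomal protein genes, 0 rose, 3 fell and 21 did not pass the test (0 and 6 adjusted over the list alone). Ribosomal protein genes had a median log2 change of -0.14 and a camera adjusted p = 0.00515, adjusted p = 0.713 with an estimated correlation. RPL11, RPL32 and RPS14 fell (-0.43, -0.34 and -0.32). For 22 mitosis genes, 0 rose, 2 fell and 20 did not pass the test (0 and 2 adjusted over the list alone). Mitosis genes had a median log2 change of -0.16 and a camera adjusted p = 0.0108, adjusted p = 0.662 with an estimated correlation. TOP2A, a DNA topoisomerase, and KIF11, a spindle kinesin, fell (-0.32 and -0.26). These 5 gene calls were lost without plasmid replicate 1, 2 or 3 or control replicate 1, those of the 3 ribosomal genes and KIF11 also without control replicate 2 and those of RPS14 and TOP2A without control replicate 3. The ribosomal list was not called without control replicate 2 or 3 and the mitosis list not without control replicate 3 or with GC and length offsets.

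The other 20 lists were not called between plasmid and control libraries. Among NF-kB targets and inflammatory cytokines 2 of 25 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.59). IL1B, the cytokine interleukin 1 beta, rose 2.8-fold and CSF3, the granulocyte growth factor, 5.55-fold, while NFKBIA, an inhibitor of NF-kB, fell (-0.93). In the TGF-beta response and matrix list 3 of 21 rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.102), the risers being the gelatinases MMP9 (4.92-fold) and MMP2 (2.21-fold, 29.5 ± 2.81 against 13.4 ± 5.07 CPM) and the matrix glycoprotein THBS1 (1.91-fold). Of epithelial keratins and junction genes 3 of 20 rose and 1 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.532), with KRT8 and KRT18, the keratins of simple epithelia, up 1.59-fold and 1.54-fold and the tight junction gene CLDN1 down (-0.54). Of airway ion transport genes 1 of 10 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.102), namely ANO1, a calcium-activated chloride channel (2.5-fold). Of p53 targets 0 of 24 rose and 3 fell (0 and 3 adjusted over the list alone, camera adjusted p = 0.169). Of ATF4 and amino acid stress genes 0 of 22 rose and 1 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.401). For cholesterol synthesis 0 of 24 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.0577), with a median log2 change of 0.40. Among interferons and interferon-induced chemokines 1 of 8 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.638), the riser being IFNK, an interferon of keratinocytes, at 0.817 ± 0.485 against 0.104 ± 0.111 CPM. Among immediate early and MAPK response genes 2 of 24 rose and 2 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.0877), with the growth factor inhibitor SPRY4 and the transcription factor ETV4 up and FOS and JUNB down. For NRF2 and oxidative stress 0 of 13 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.401). For lysosome and autophagy 0 of 20 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.169). Of DNA replication genes 1 of 22 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.223). Of base excision and mismatch repair genes 1 of 19 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.401). Among nonsense-mediated decay factors 0 of 14 rose and 3 fell (0 and 6 adjusted over the list alone, camera adjusted p = 0.132). Of replication-dependent histones 0 of 13 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.484). Of secretory, ciliated and ionocyte markers 0 of 7 rose and 1 fell (0 and 1 adjusted over the list alone, camera adjusted p = 0.532). Of squamous differentiation genes 2 of 10 rose and 0 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.35). Of fibroblast markers 2 of 4 rose and 0 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.182). Of leukocyte markers 2 of 5 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.132). Of HEK293 producer cell markers 1 of 9 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.638). Every gene call named in this paragraph was lost without plasmid replicate 1 or control replicate 1, and all but those of MMP9 and ANO1 without plasmid replicate 3. CLDN1, SPRY4, ETV4 and FOS also lost it without plasmid replicate 2, and THBS1 and JUNB without control replicate 2.

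In all, 1624 of 17984 genes changed between plasmid and control libraries, 793 higher and 831 lower, and 437 of them by a log2 of at least 1 (335 higher and 102 lower). Upper-quartile scaling gave 912 higher and 612 lower, and GC and length offsets 859 and 689. Groups did not overlap for 29.8% of all genes tested, where chance gives 10%. The count was 43, 948 and 106 without plasmid replicate 1, 2 and 3, 80 without control replicate 1, 540 in a fit of the 6 libraries alone, 400 against the mock-transfected library and 106 against both mock libraries, but 3036 with no filter and 2488 by DESeq2. Of 76 called genes singled out by the naming rule, 12 stayed called whichever library was left out: HSPA6, HSPA1A, HSPA1B, BAG3, DNAJB1, MT-ATP6, MT-CO1, MT-ND2, ADAM19, KLKP1, AC083899.2 and AL591846.1.

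**Figure D1:**
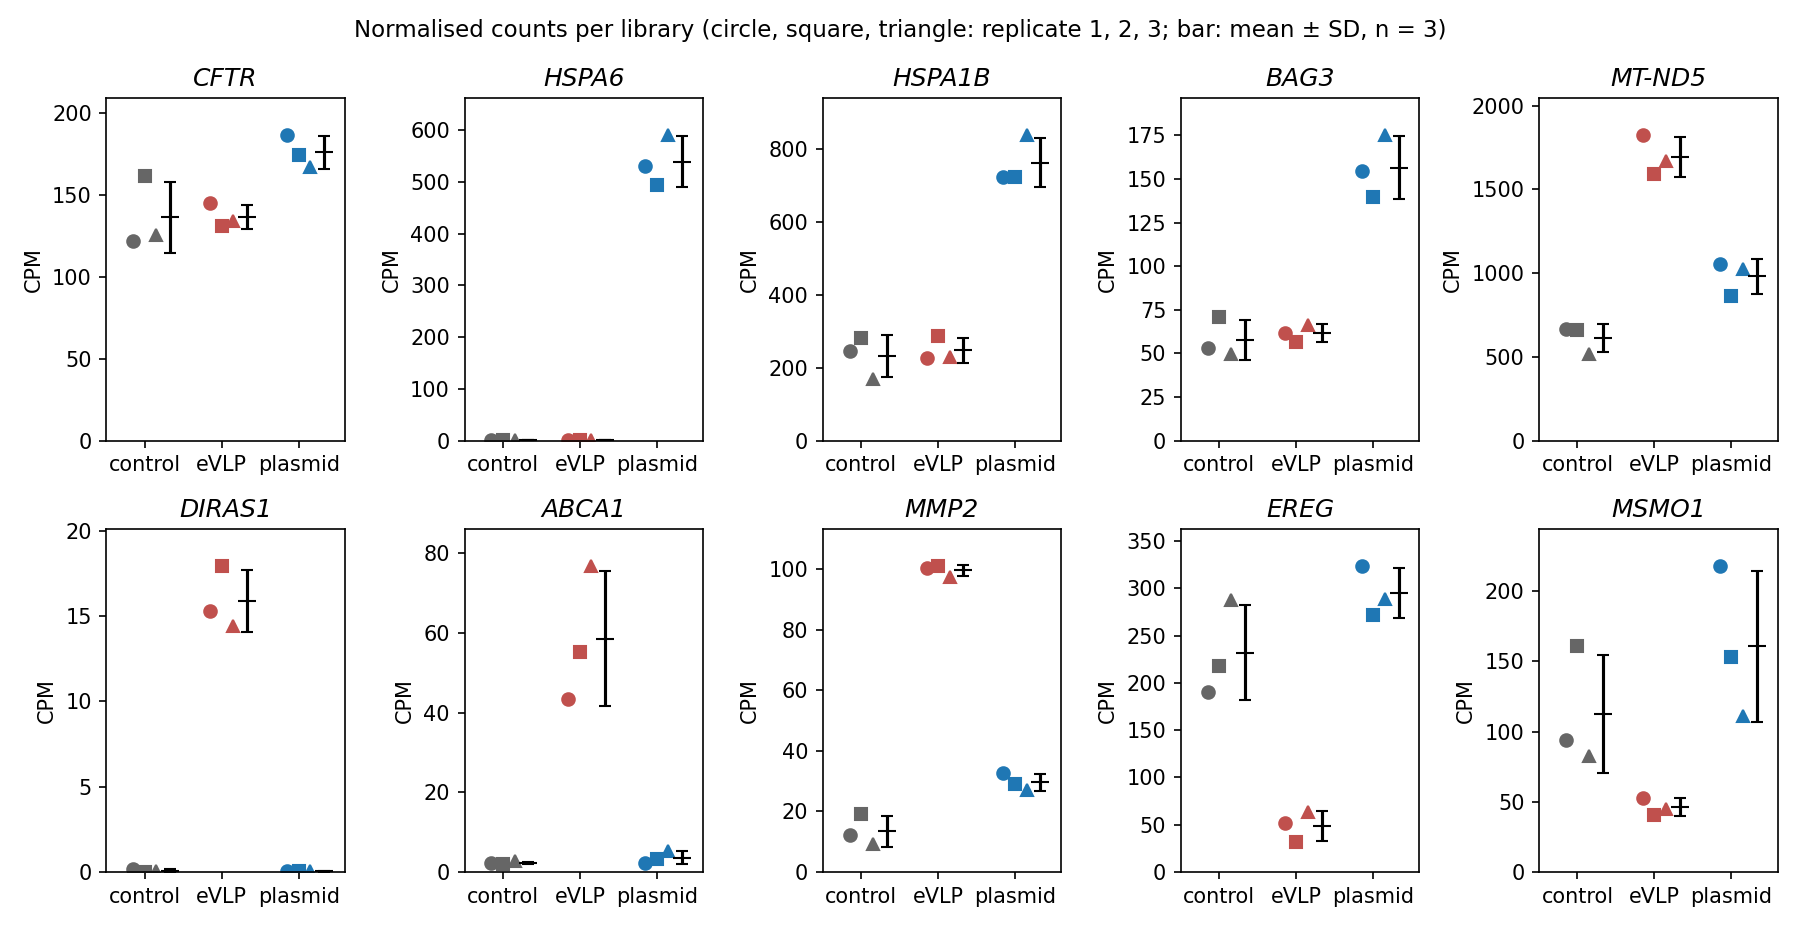
Normalised level (CPM, linear axis from 0) of 10 genes in each of the 9 libraries, with points for libraries and a black bar beside them for the group mean ± SD (n = 3). HSPA6 stood at 539 ± 49 CPM in plasmid libraries and DIRAS1 at 15.9 ± 1.83 CPM in eVLP libraries, against 1.73 ± 0.391 and 0.0685 ± 0.0845 CPM in control libraries.

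The comparison of eVLP with control libraries asks how particle delivery changed the cells. DIRAS1 (ENSG00000176490, GRCh38 chromosome 19, 2714567 to 2721418), a small GTPase of the RAS family, rose from 0.0685 ± 0.0845 to 15.9 ± 1.83 CPM (adjusted p = 3.46e-05), from 10 counts over the control libraries to 1446 over the eVLP libraries. The ratio of these counts per depth was 204, with a 95% counting interval of 111 to 427. This interval covers counting only: the control counts of DIRAS1 were 8, 0 and 2 per library, and its fitted log2 change of 7.61 ran from 7.20 without control replicate 2 to 12.1 against the mock-transduced library alone. ABCA1 (ENSG00000165029, GRCh38 chromosome 9, 104781002 to 104928237), which exports cholesterol from cells, rose 24.9-fold, 58.5 ± 16.9 against 2.33 ± 0.26 CPM, adjusted p = 0.000128. ACKR3, a chemokine scavenger receptor, rose 22.1-fold (6.63 ± 1.17 against 0.319 ± 0.212 CPM), NKAIN4, which binds a sodium pump subunit, 20.3-fold, SPOCD1 17.2-fold, and BASP1, a membrane-bound signalling protein, 14.6-fold. FGFBP1, which releases fibroblast growth factors from the matrix, fell by 2.56 on the log2 scale, and the chemokine CCL20 fell by 2.35 (2.91 ± 0.89 against 14.8 ± 3.22 CPM). EREG and EPGN, ligands of the epidermal growth factor receptor, fell (-2.25 and -1.69), as did TXNIP, a glucose-responsive inhibitor of thioredoxin (-1.98), and the noncoding RNA LY6E-DT (-1.72).

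Matrix and TGF-beta response genes rose in eVLP libraries. Of 21 measured members, 15 rose, 0 fell and 6 did not pass the test (15 and 0 adjusted over the list alone). Matrix and TGF-beta genes had a median log2 change of 1.31 and a camera adjusted p = 1.58e-28, adjusted p = 0.00192 with an estimated correlation, still under 0.05. MMP2 (ENSG00000087245, GRCh38 chromosome 16, 55389700 to 55506691), a gelatinase, rose 7.47-fold, 99.6 ± 1.91 against 13.4 ± 5.07 CPM, adjusted p = 0.000153, and SKIL, a feedback inhibitor of TGF-beta signalling, rose 2.16-fold, 278 ± 10.5 against 129 ± 12.6 CPM, adjusted p = 0.000153. The basement membrane collagens COL4A1 and COL4A2 rose 2.27-fold (642 ± 19.8 against 283 ± 35.4 CPM) and 1.94-fold (1266 ± 49 against 653 ± 27.2 CPM). Among 17 hypoxia and glycolysis genes, 11 rose, 0 fell and 6 did not pass the test (12 and 0 adjusted over the list alone). Hypoxia and glycolysis genes had a median log2 change of 0.60 and a camera adjusted p = 3.17e-08, adjusted p = 0.248 with an estimated correlation. PFKFB3 and PFKFB4, regulators of glycolysis, rose 2.12-fold and 2.0-fold, PDK1, which limits pyruvate oxidation, 1.85-fold, and the mitophagy gene BNIP3 1.63-fold. Lysosome and autophagy genes numbered 20, of which 8 rose, 0 fell and 12 did not pass the test (8 and 0 adjusted over the list alone). Lysosome genes had a median log2 change of 0.27 and a camera adjusted p = 0.00315, adjusted p = 0.496 with an estimated correlation. LAMP2, a lysosomal membrane protein, rose 1.37-fold and SQSTM1, an autophagy receptor, 1.47-fold, though neither gene nor the list was called against the mock-transduced library alone.

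Mitochondrial genes took 2.08 ± 0.134% of all counts in eVLP and 0.994 ± 0.0888% in control libraries. Of the 13 mitochondrially encoded mRNAs measured, 12 rose, 0 fell and 1 did not pass the test (12 and 0 adjusted over the list alone). Mitochondrial mRNAs had a median log2 change of 0.97 and a camera adjusted p = 5.79e-29, adjusted p = 0.0455 with an estimated correlation, still under 0.05. MT-ATP6 rose 2.04-fold, 1787 ± 30.6 against 877 ± 65.1 CPM, adjusted p = 0.000153, and the complex I subunits MT-ND4, MT-ND5 and MT-ND6 rose 2.41-fold, 2.76-fold and 2.78-fold. MT-ND6 lies antisense to the end of MT-ND5 mRNA, and nuclear copies share mitochondrial sequence, so reads of these genes may not all be told apart.

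Ribosomal protein mRNAs fell almost as a whole: of 24 members, 0 rose, 23 fell and 1 did not pass the test (0 and 23 adjusted over the list alone). Ribosomal protein genes had a median log2 change of -0.71 and a camera adjusted p = 1.58e-28, adjusted p = 0.197 with an estimated correlation. Examples were RPS14 (log2 change -0.82, 906 ± 62.1 against 1596 ± 100.3 CPM, adjusted p = 0.00048), RPS18 (-0.92) and RPL32 (-0.72). Of 22 ATF4 and amino acid stress genes, 1 rose, 14 fell and 7 did not pass the test (1 and 17 adjusted over the list alone). ATF4 genes had a median log2 change of -0.62 and a camera adjusted p = 1.97e-09, adjusted p = 0.244 with an estimated correlation. The transcription factor CEBPB fell (log2 change -0.87, 235 ± 5.3 against 429.8 ± 37.5 CPM, adjusted p = 0.000298), and so did DDIT4, an inhibitor of mTORC1 (-0.88), the pseudokinase TRIB3 (-1.17) and CHAC1, which degrades glutathione (-1.47). Of 24 genes of the cholesterol synthesis list, 0 rose, 12 fell and 12 did not pass the test (0 and 17 adjusted over the list alone). Cholesterol genes had a median log2 change of -0.77 and a camera adjusted p = 3.85e-08, adjusted p = 0.498 with an estimated correlation. MSMO1, an enzyme of the pathway, fell (log2 change -1.29, 46 ± 6.35 against 112 ± 42.2 CPM, adjusted p = 0.00974), with CYP51A1, another, at -1.15 and its transcription factor SREBF2 at -0.79. For fatty acid synthesis and lipid storage, 1 rose, 4 fell and 9 did not pass the test (1 and 6 adjusted over the list alone) of 14 members. Fatty acid genes had a median log2 change of -0.34 and a camera adjusted p = 0.0289, adjusted p = 0.496 with an estimated correlation. ACLY, which makes acetyl-CoA from citrate, fell (-0.45), as did the desaturase FADS1 (-0.43), but the list was not called without eVLP replicate 3 or without control replicate 2.

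Called downward at the preset correlation were also the immediate early, inflammatory and keratin lists, with many members not past the test. Of 24 immediate early and MAPK response genes, 2 rose, 10 fell and 12 did not pass the test (3 and 13 adjusted over the list alone). Immediate early genes had a median log2 change of -0.72 and a camera adjusted p = 6.37e-05, adjusted p = 0.288 with an estimated correlation. EREG fell from 232 ± 49.8 to 48.9 ± 15.8 CPM, AREG, another ligand of the same receptor, by 1.65 on the log2 scale and the feedback inhibitor SPRY2 by 1.03, while the transcription factor FOSB rose 4.61-fold. Of 25 NF-kB targets and inflammatory cytokines, 1 rose, 7 fell and 17 did not pass the test (1 and 9 adjusted over the list alone). Inflammatory genes had a median log2 change of -0.31 and a camera adjusted p = 0.00445, adjusted p = 0.307 with an estimated correlation. The neutrophil chemokine CXCL8 and the cytokine IL1A fell (-1.32 and -1.11), besides CCL20. Of 20 epithelial keratins and junction genes, 2 rose, 10 fell and 8 did not pass the test (3 and 12 adjusted over the list alone). Keratins and junction genes had a median log2 change of -0.33 and a camera adjusted p = 0.00535, adjusted p = 0.498 with an estimated correlation. KRT18 fell (log2 change -0.84, 801 ± 22.1 against 1434 ± 157 CPM, adjusted p = 0.00179), as did KRT8 (-0.66), the tight junction gene OCLN (-0.77) and ESRP1, an epithelial splicing factor (-0.44), but the list was not called without control replicate 2.

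Interferon-stimulated genes did not rise as a group: of 40, 1 rose, 6 fell and 33 did not pass the test (1 and 5 adjusted over the list alone). Interferon-stimulated genes had a median log2 change of -0.14 and a camera adjusted p = 0.0398, adjusted p = 0.856 with an estimated correlation. IFIT1, IFIT5, IFITM2 and IFITM3, antiviral effectors, fell (-0.78, -0.96, -0.78 and -0.91). Of 16 nucleic acid sensing genes, 0 rose, 3 fell and 13 did not pass the test (0 and 6 adjusted over the list alone). Nucleic acid sensing genes had a median log2 change of -0.26 and a camera adjusted p = 0.0158, adjusted p = 0.498 with an estimated correlation. ZCCHC3, a cofactor of cytosolic sensors, fell (-0.51), and DDX58, the RNA sensor RIG-I, fell (-0.52), though not without eVLP replicate 2 or 3. Of 14 nonsense-mediated decay factors, 0 rose, 4 fell and 10 did not pass the test (0 and 4 adjusted over the list alone). Decay factors had a median log2 change of -0.13 and a camera adjusted p = 0.0396, adjusted p = 0.509 with an estimated correlation. Among those that fell were the exon junction genes RBM8A (-0.45) and MAGOH (-0.38). The interferon list was not called by limma-voom or without eVLP replicate 3, control replicate 1 or control replicate 2, the sensing list without eVLP replicate 3 or control replicate 2, and the decay list without eVLP replicate 2, control replicate 1 or control replicate 3. The decay list was also lost with upper-quartile scaling, in only the 6 libraries, with the replicate block, with GC and length offsets and against its own mock library, and both it and the interferon list against both mock libraries.

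The remaining 16 lists were not called between eVLP and control libraries. Of cytosolic heat shock genes 0 of 13 rose and 5 fell (1 and 5 adjusted over the list alone, camera adjusted p = 0.0528), with DNAJB1 at -0.46 and the mitochondrial chaperone HSPD1 at -0.60, and HSPA6 stood at 1.74 ± 0.503 CPM in eVLP libraries. Of unfolded protein response genes 5 of 20 rose and 3 fell (7 and 4 adjusted over the list alone, camera adjusted p = 0.132), with CRELD2, an ER stress-inducible factor, up 1.7-fold. Of p53 targets 2 of 24 rose and 6 fell (3 and 8 adjusted over the list alone, camera adjusted p = 0.0528), with the stress cytokine GDF15 down (-1.33). Among squamous differentiation genes 1 of 10 rose and 2 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.771), with IVL, a cornified envelope protein, up 4.15-fold (30.8 ± 2.71 against 7.46 ± 2.92 CPM) and S100A9 down (-1.38); this list had a median of 0.058, a mean of -0.33 and a test that pointed down. Among HEK293 producer cell markers 2 of 9 rose and 2 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.889), with a median of -0.33, a mean of 0.81 and a test that pointed down. NEFM, a neurofilament gene, rose from 7 to 160 counts (ratio per depth 32.3, counting interval 15.3 to 81.6), and NEFL, another, stood at 1 count over the control and 48 over the eVLP libraries (ratio 67.8, interval 11.6 to 2734). MAP2 and HOXA9, of the same list, fell (-0.99 and -0.74). Of fibroblast markers 1 of 4 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.0826), COL6A3 at 0.539 ± 0.313 against 0.0998 ± 0.0359 CPM, not called without eVLP replicate 3 or control replicate 1. Of leukocyte markers 1 of 5 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.342), LAPTM5. For airway ion transport 1 of 10 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.889), with the sodium channel gene SCNN1A and the potassium channel gene KCNN4 down (-0.83 and -0.79) and the sodium pump gene ATP1B1 up 1.31-fold. For mitosis 1 of 22 rose and 5 fell (1 and 8 adjusted over the list alone, camera adjusted p = 0.0528), with a median log2 change of -0.18. MKI67, the proliferation marker Ki-67, was the 1 that rose (1.37-fold), while 16 of the 22 members were lower. For MHC class I antigen presentation 0 of 17 rose and 2 fell (0 and 2 adjusted over the list alone, camera adjusted p = 0.66), where the median was 0.044, the mean -0.0070 and the test pointed down. For DNA replication 1 of 22 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.889), where the median was -0.018, the mean 0.035 and the test pointed up. Of base excision and mismatch repair genes 2 of 19 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.889). Of replication-dependent histones 3 of 13 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.132). Of secretory, ciliated and ionocyte markers 1 of 7 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.559). Of interferons and interferon-induced chemokines 1 of 8 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.84). Of NRF2 and oxidative stress genes 0 of 13 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.587).

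In all, 4082 of 17984 genes changed between eVLP and control libraries, 1957 higher and 2125 lower, and 974 by a log2 of at least 1 (841 higher and 133 lower). The balance depended on the scaling, with 2622 higher and 1274 lower by upper-quartile scaling and 2218 and 1633 with GC and length offsets. Groups did not overlap for 39.8% of genes, against 10% by chance. A fit of only the 6 libraries called 2950 genes. The count fell to 2215 without eVLP replicate 1, 2557 without eVLP replicate 2 and 1782 against the mock-transduced library alone. Of 105 called genes singled out by the naming rule, 84 stayed called whichever library was left out, while against the mock-transduced library alone ACLY, FADS1, ESRP1, ZCCHC3, MAGOH, HSPD1, LAPTM5 and NEFL, among others, were not called.

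The comparison of plasmid with eVLP libraries sets the delivery methods side by side. HSPA6 was 318-fold higher in plasmid libraries (539 ± 49 against 1.74 ± 0.503 CPM, adjusted p = 2.93e-08), and DIRAS1 was lower (log2 change -8.30, 0.0461 ± 0.0293 against 15.9 ± 1.83 CPM, adjusted p = 2.45e-05). Of 13 cytosolic heat shock genes, 12 rose, 0 fell and 1 did not pass the test (13 and 0 adjusted over the list alone). Heat shock genes had a median log2 change of 0.81 and a camera adjusted p = 1.02e-19, adjusted p = 0.0306 with an estimated correlation, still under 0.05. DNAJB1 was 2.29-fold higher (541 ± 49.6 against 236 ± 4.36 CPM), BAG3 2.55-fold and HSPA1B 3.07-fold. The mitochondrial chaperone gene HSPD1, which this list also holds despite its name, was 2.3-fold higher. Higher in plasmid libraries were also COL13A1, a transmembrane collagen (17.4-fold), KRT33B (15.1-fold), AC083899.2 (14.9-fold), FGFBP1 (11.7-fold) and IL1RL1, the interleukin 33 receptor (10.9-fold). Lower were NKAIN4 (-4.65), ACKR3 (-4.13), the cholesterol exporters ABCA1 (-4.01) and ABCG1 (log2 change -3.53, 1.85 ± 0.605 against 21.5 ± 7.47 CPM, adjusted p = 0.000779), and RN7SL3 (ENSG00000278771, GRCh38 chromosome 14, 49853616 to 49853914), an RNA of the signal recognition particle (log2 change -3.84, 0.348 ± 0.0315 against 5.05 ± 0.87 CPM, adjusted p = 0.000113).

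The cholesterol, fatty acid, ribosomal protein and ATF4 lists were called upward in plasmid against eVLP libraries at the preset correlation. Of 24 cholesterol genes, 19 rose, 1 fell and 4 did not pass the test (20 and 1 adjusted over the list alone). Cholesterol genes had a median log2 change of 1.15 and a camera adjusted p = 9.35e-12, adjusted p = 0.394 with an estimated correlation. MSMO1 was 3.5-fold higher (161 ± 53.8 against 46 ± 6.35 CPM), CYP51A1 3.09-fold and FDFT1, squalene synthase, 2.67-fold. Of 14 genes of fatty acid synthesis and lipid storage, 10 rose, 0 fell and 4 did not pass the test (10 and 0 adjusted over the list alone). Fatty acid genes had a median log2 change of 0.57 and a camera adjusted p = 6.47e-05, adjusted p = 0.25 with an estimated correlation. Among the risers were ELOVL6, a fatty acid elongase (2.94-fold), and FASN (1.76-fold). Of 24 ribosomal protein genes, 21 rose, 0 fell and 3 did not pass the test (23 and 0 adjusted over the list alone). Ribosomal protein genes had a median log2 change of 0.53 and a camera adjusted p = 1.67e-15, adjusted p = 0.25 with an estimated correlation. RPS2 and RPS3 were 1.99-fold and 1.73-fold higher. Of 22 ATF4 and amino acid stress genes, 14 rose, 1 fell and 7 did not pass the test (15 and 2 adjusted over the list alone). ATF4 genes had a median log2 change of 0.58 and a camera adjusted p = 6.83e-07, adjusted p = 0.25 with an estimated correlation. TRIB3 was 2.16-fold higher, CTH, which makes cysteine, 2.09-fold, and SHMT2, of mitochondrial one-carbon metabolism, 1.65-fold.

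At the preset correlation the immediate early, inflammatory and keratin lists were called upward in plasmid against eVLP libraries. Of 24 immediate early and MAPK response genes, 16 rose, 4 fell and 4 did not pass the test (16 and 5 adjusted over the list alone). Immediate early genes had a median log2 change of 1.11 and a camera adjusted p = 1.36e-07, adjusted p = 0.191 with an estimated correlation. EREG was 6.04-fold higher (295 ± 26.3 against 48.9 ± 15.8 CPM), AREG 4.71-fold, SPRY4 3.04-fold and SPRY2 2.25-fold. Of 25 NF-kB targets and inflammatory cytokines, 9 rose, 1 fell and 15 did not pass the test (9 and 1 adjusted over the list alone). Inflammatory genes had a median log2 change of 0.29 and a camera adjusted p = 0.0011, adjusted p = 0.25 with an estimated correlation. CCL20 was 4.02-fold higher, IL1A 3.73-fold and LIF, a cytokine of the interleukin 6 family, 2.55-fold. Of 20 epithelial keratins and junction genes, 7 rose, 3 fell and 10 did not pass the test (7 and 4 adjusted over the list alone). Keratins and junction genes had a median log2 change of 0.26 and a camera adjusted p = 0.0011, adjusted p = 0.448 with an estimated correlation. This list was not called in the fit with the replicate block and GC and length offsets. KRT18 and KRT8 were 2.75-fold and 2.53-fold higher, OCLN 2.08-fold and CLDN7, a claudin, 2.15-fold.

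Downward calls in plasmid against eVLP libraries at the preset correlation were those of the matrix, mitochondrial, lysosome, hypoxia and antigen presentation lists. Of 21 TGF-beta response and matrix genes, 0 rose, 13 fell and 8 did not pass the test (1 and 17 adjusted over the list alone). Matrix and TGF-beta genes had a median log2 change of -1.01 and a camera adjusted p = 1.02e-19, adjusted p = 0.00457 with an estimated correlation, still under 0.05. The fibrillar collagen COL5A1 fell (log2 change -2.30, 107 ± 22.4 against 530.1 ± 59.4 CPM, adjusted p = 0.00015), with LTBP2, which binds microfibrils, at -1.68 and the TGF-beta target PMEPA1 at -1.46. Of 13 mitochondrial mRNAs, 0 rose, 7 fell and 6 did not pass the test (0 and 10 adjusted over the list alone). Mitochondrial mRNAs had a median log2 change of -0.34 and a camera adjusted p = 8.59e-06, adjusted p = 0.347 with an estimated correlation. MT-ND6 stood at -1.17 and MT-ND5 at -0.79, beside mitochondrial shares of 1.54 ± 0.0304% and 2.08 ± 0.134%. Of 20 lysosome and autophagy genes, 0 rose, 10 fell and 10 did not pass the test (0 and 10 adjusted over the list alone). Lysosome genes had a median log2 change of -0.36 and a camera adjusted p = 4.02e-05, adjusted p = 0.285 with an estimated correlation. LAMP2 and LAMP1 fell (-0.63 and -0.57). Of 17 hypoxia and glycolysis genes, 0 rose, 7 fell and 10 did not pass the test (0 and 7 adjusted over the list alone). Hypoxia and glycolysis genes had a median log2 change of -0.48 and a camera adjusted p = 0.000835, adjusted p = 0.448 with an estimated correlation. BNIP3 and KDM3A, a histone demethylase, fell (-0.72 and -0.91). Of 17 MHC class I antigen presentation genes, 0 rose, 6 fell and 11 did not pass the test (0 and 11 adjusted over the list alone). Antigen presentation genes had a median log2 change of -0.53 and a camera adjusted p = 0.0011, adjusted p = 0.761 with an estimated correlation. NLRC5, the activator of this gene class, fell (log2 change -1.50, 25.5 ± 7.21 against 71.9 ± 17.9 CPM, adjusted p = 0.00411), as did B2M, the light chain (-0.95).

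The other 17 lists were not called between plasmid and eVLP libraries. Of interferon-stimulated genes 3 of 40 rose and 4 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.424), with a median log2 change of -0.28. IFITM3 (1.82-fold) and IFIT5 (1.66-fold) were higher in plasmid libraries, while 26 of the 40 members were lower. Of interferons and interferon-induced chemokines 0 of 8 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.963), the T cell chemokine CXCL10 at 1.65 ± 0.141 against 2.86 ± 1.0 CPM (adjusted p = 0.0582, but 0.0196 with the replicate number as a block). For nucleic acid sensing 4 of 16 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.691), with the DNA sensor CGAS up 1.53-fold, a call lost without plasmid replicate 1, plasmid replicate 3 or eVLP replicate 2; the median was -0.021, the mean 0.064 and the test pointed up. Of p53 targets 7 of 24 rose and 5 fell (7 and 5 adjusted over the list alone, camera adjusted p = 0.531), with GDF15 up 2.44-fold and TP53I3, an oxidoreductase, down (-0.80). For the unfolded protein response 5 of 20 rose and 1 fell (5 and 1 adjusted over the list alone, camera adjusted p = 0.217), with the ER chaperone cofactor DNAJB9 up 1.49-fold. Among airway ion transport genes 4 of 10 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.199), with ANO1 up 2.52-fold (84.2 ± 24.8 against 33.4 ± 8.44 CPM), KCNN4 1.98-fold, SCNN1A 1.63-fold and CFTR as given above, and ATP1B1 down (-0.44). Among HEK293 producer cell markers 3 of 9 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.657), with a median of 0.29, a mean of -0.81 and a test that pointed up. HOXA9 was 1.75-fold higher in plasmid libraries, and NEFL had 0 counts in them, against 48 over the eVLP libraries, a ratio per depth with a lower 95% counting limit of 14.9. Among squamous differentiation genes 3 of 10 rose and 3 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.398), with S100A9 up 3.39-fold. For mitosis 1 of 22 rose and 5 fell (2 and 5 adjusted over the list alone, camera adjusted p = 0.848), with a median of 0.024, a mean of -0.0054 and a test that pointed down. Of DNA replication genes 0 of 22 rose and 4 fell (0 and 4 adjusted over the list alone, camera adjusted p = 0.327). For base excision and mismatch repair 2 of 19 rose and 5 fell (2 and 6 adjusted over the list alone, camera adjusted p = 0.657). Of nonsense-mediated decay factors 0 of 14 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.527). For NRF2 and oxidative stress 2 of 13 rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.263). Of replication-dependent histones 1 of 13 rose and 2 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.461). For secretory, ciliated and ionocyte markers 0 of 7 rose and 0 fell (0 and 0 adjusted over the list alone, camera adjusted p = 0.309). Of fibroblast markers 1 of 4 rose and 1 fell (1 and 2 adjusted over the list alone, camera adjusted p = 0.657). For leukocyte markers 1 of 5 rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.848), with a median of -0.60, a mean of -0.12 and a test that pointed up.

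In all, 4736 of 17984 genes changed between plasmid and eVLP libraries, 2459 higher in plasmid and 2277 higher in eVLP libraries, and 1224 by a log2 of at least 1 (472 and 752). With upper-quartile scaling the numbers were 1915 and 2836. Groups did not overlap for 47.8% of genes, against 10% by chance. The replicate numbers were taken to pair these libraries, from the data and not from the labels. A fit of only the 6 libraries called 5818 genes, the replicate block in all 9 called 5979, and both choices together, a setting added after the data had been seen, called 7508 (3893 and 3615). Of the 8 genes singled out by the naming rule that were not called here, these fits called 6, 6 and 7. The count without 1 library fell to 2353 without plasmid replicate 1, 3119 without plasmid replicate 3, 2948 without eVLP replicate 1 and 2600 without eVLP replicate 2. Of 112 called genes singled out by the naming rule, 89 stayed called whichever library was left out.

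Genes called against control in both treatments numbered 620, of which 248 were higher in both, 313 lower in both and 59 changed in opposite directions. Independent lists of these sizes would share 86.3, 98.2 and 184 genes. In 50 simulations all 9 libraries were drawn from the mean control levels, so that no gene changed and both comparisons shared the simulated controls. These gave means of 0.04, 0 and 0, but few genes can be called where none changes. They therefore do not show how many shared calls come from the controls. Replicate effects shared by same-numbered plasmid and eVLP libraries were not simulated. The correlation of log2 changes across genes, which are not independent replicates, was 0.292, against 0.469 in the simulations, and the covariance was 0.0957 against 0.0445. The simulations gave all groups the same spread, whereas the real control pairs lay furthest apart. The simulated covariance may therefore be too low, and its difference from the observed value does not show a shared response. Since both comparisons use the same 3 control libraries, part of the shared calls may come from these libraries. The 561 calls of shared direction fell to 35 without control replicate 1, 73 against each treatment's own mock library and 6 at adjusted p under 0.01, and came to 849 without control replicate 2. ADAM19 and MMP9 were among the genes higher in both, at log2 changes of 2.78 and 2.30 in plasmid and 1.71 and 3.85 in eVLP libraries. HSPB8, a small heat shock protein chosen after its values were seen, rose in both (2.45 and 2.10), and KISS1, chosen in the same way, rose in plasmid and fell in eVLP libraries (2.12 and -1.25).

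**Figure D2:**
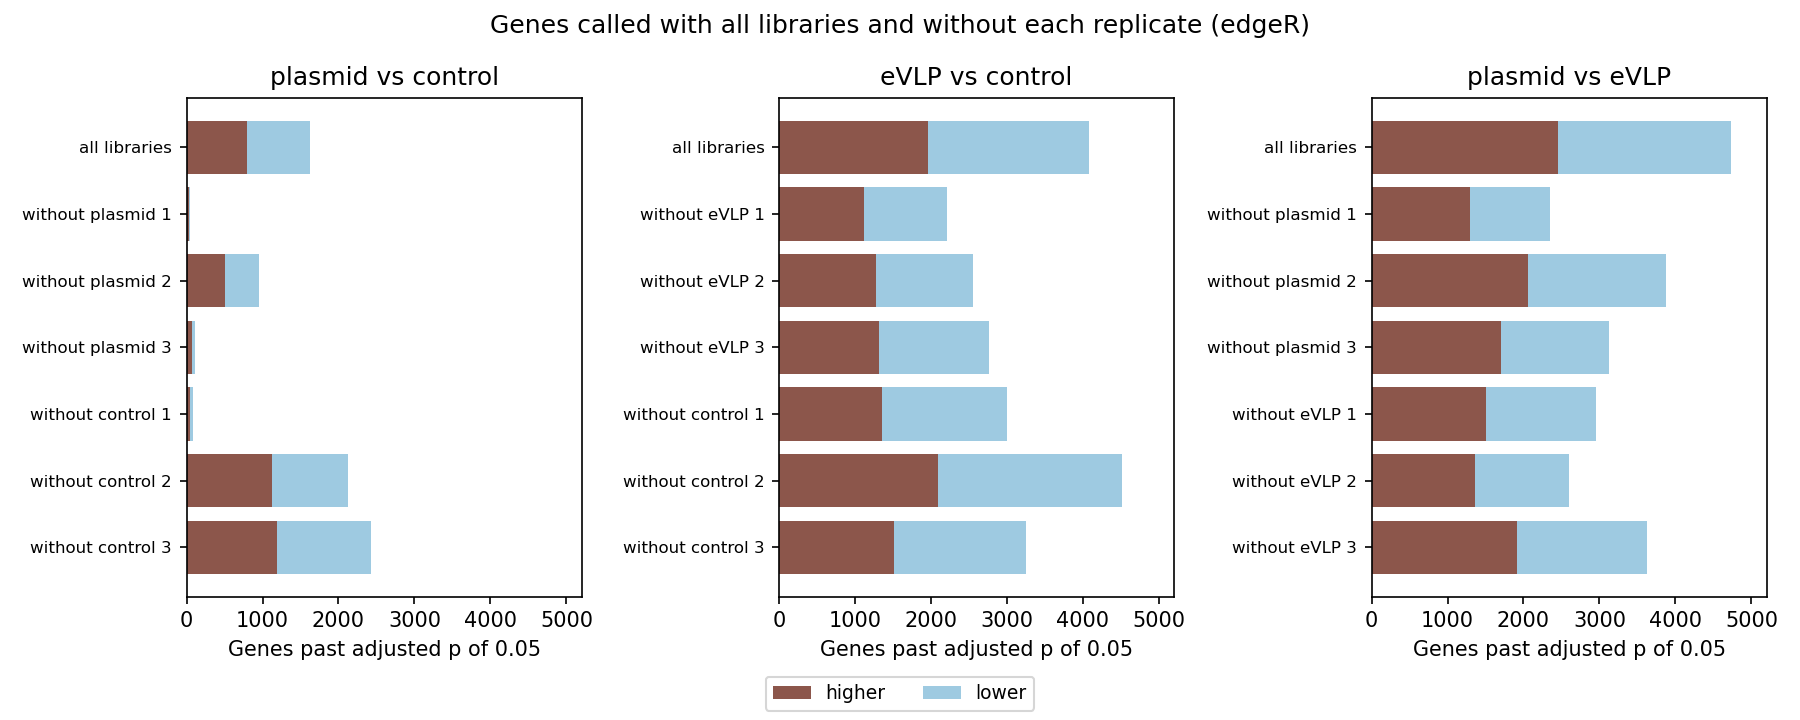
Number of genes called by edgeR (horizontal axis) in each comparison with all libraries and without each of its libraries in turn, split into genes higher and lower. With a library left out the plasmid against control count ranged from 43 to 2425 (1624 with all), the eVLP against control count from 2215 to 4508 (4082 with all), and the plasmid against eVLP count from 2353 to 3880 (4736 with all).

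The authors' deposited tables hold their own comparisons, with 1879 genes at adjusted p under 0.05 for plasmid against control (994 higher and 885 lower), 3531 for eVLP against control (1732 and 1799) and 5705 for eVLP against plasmid (2683 and 3022). Of these, 1437, 3308 and 4509 were also called here, each in the same direction. CFTR stood in the authors' deposited tables at log2 changes of 0.37 (adjusted p = 0.0624), 0.0076 (0.980) and -0.36 (0.000253), the last for eVLP against plasmid. The authors' deposited tables of Gene Ontology terms gave 13 of 215 angiogenesis genes for plasmid against control (adjusted p = 2.74e-05), 27 of 452 cell adhesion genes for eVLP against control (3.42e-06) and 38 of 385 immune response genes for plasmid against eVLP (1.05e-09).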

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

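The GC and length offsets, the replicate block with these offsets and the block in only the 6 libraries were chosen after the data had been seen; the other alternatives were planned. Where no cause is given, the cause was not tested; leaving out libraries or genes changes the number of samples or tests. For plasmid against control, 1624 genes (793 higher and 831 lower) became 3036 (1539 and 1497) with no filter, 2488 (1071 and 1417) by DESeq2, 540 (315 and 225) in only the 6 libraries, 400 (222 and 178) against its own mock library, of which 224 were among the 1624, and 106 (57 and 49) against both mock libraries. Without 1 library the count ranged from 43 to 2425, with 35 to 1188 higher and 8 to 1237 lower. For eVLP against control, 4082 (1957 and 2125) became 1782 (654 and 1128) against its own mock library and 2908 (1292 and 1616) against both, and 2215 to 4508 without 1 library (1115 to 2088 higher and 1100 to 2420 lower). For plasmid against eVLP, 4736 (2459 and 2277) became 2353 to 3880 without 1 library (1293 to 2055 higher and 1060 to 1825 lower). A lone mock library was assumed to vary like the other groups. Upper-quartile scaling gave 912 higher and 612 lower (59.8% higher, against 48.8%), 2622 and 1274 (67.3% against 47.9%) and 1915 and 2836 (40.3% against 51.9%). RLE scaling, limma-voom, robust estimation and the filter of 10 counts kept each total within 1.5 times. With the replicate block, plasmid against control gave 2955 (1470 and 1485) and eVLP against control 5365. There the replicate numbers did not pair all libraries (correlations of -0.06, 0.21 and 0.32, and of -0.01, 0.18 and 0.40). Control replicate 3 was nonetheless the best match of plasmid and eVLP replicate 3. Each kind of control has its own replicate number, so the 2 cannot be told apart. For plasmid against eVLP only the 6 libraries gave 5818 and the block 5979, 5979 (2816 and 3163) with the offsets and 7508 (3893 and 3615) in only the 6 libraries, and of the list calls only that of keratins and junctions was lost, in the block with offsets.

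CFTR from control to plasmid passed at 0.39 with upper-quartile scaling (adjusted p = 0.0442), 0.35 by DESeq2 (0.0324), 0.38 by limma-voom (0.0486), 0.35 with no filter (0.0094), 0.37 with the block (0.0356) and 0.43 with the offsets (0.0482); without 1 library it was 0.29 to 0.50, and it passed without control replicate 2 (0.0093). From eVLP to plasmid it missed at 0.30 with upper-quartile scaling (0.0540) and at 0.33 to 0.41 without 1 library, and it passed with the block (0.0217), in only the 6 libraries (0.00498), with both (0.000496) and by DESeq2 (0.0134). Its value from control to eVLP, never called, was -0.0043 with RLE scaling, -0.021 by DESeq2, -0.030 with no filter, -0.24 against its own mock library, -0.078 against both and -0.074 to 0.14 without 1 library. NQO1 from control to eVLP, not called, was 0.024 against its own mock library, and the interferon-stimulated genes from control to plasmid had a median of 0.045 there (adjusted p = 0.694). Called lists from control to plasmid numbered 18 with no filter and 16 against its own mock library, and with an estimated correlation 0, 2 and 2 lists were called in the 3 comparisons. Shared calls of the treatments, 561, were 6 at adjusted p under 0.01, 93 at an absolute log2 change of at least 1, 73 with own mocks and 35 to 849 without 1 library. The authors' deposited tables gave 426, 796 and 1175 genes at an absolute log2 change of at least 1.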

Other observations

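The tests of HSPA6, the test of 7SL RNA and the requirement of more than 9 counts for producer-cell markers and the sums over silent markers were chosen after the results were seen.

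Cholesterol export genes rose in eVLP libraries: ABCA1 by 24.9-fold and ABCG1, its partner in lipid efflux, by 6.17-fold (from 3.44 to 21.5 CPM), both targets of the liver X receptors, which sense oxysterols. The hypothesis of a wider liver X receptor response was tested on 9 other targets, of which 4 rose and 0 fell (4 and 0 adjusted over the list alone): MYLIP, a ubiquitin ligase (1.95-fold, 27.5 ± 3.54 against 14 ± 5.02 CPM), APOE (1.43-fold), LPCAT3 (1.38-fold) and SREBF1 (1.26-fold). The hypothesis needed a rise in at least 5 of 9, and under 3 would have spoken against it, so it stays open. In plasmid libraries 1 of the 9 rose against control. SREBF1 and SCD also belong to the fatty acid list, so for them this was not a separate test. SREBF1 was the 1 gene of that list that rose from control to eVLP libraries.

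In eVLP libraries NEFM and NEFL, markers of the HEK293 cells in which such particles are commonly made, rose from near 0. RNA of producer cells carried by the particles was tested on the 6 other listed markers with a control mean under 0.5 CPM, of which 1, ZNF423, was higher in every eVLP library than in any control library. That meets the bound of under 2 of 6 set against this explanation. Together these 6 had 16 counts over the control and 13 over the eVLP libraries. The ratio per depth was 1.15 (95% counting interval 0.508 to 2.55), so as a set they showed no clear rise. Each had only 0 to 8 counts over the eVLP libraries, at most 0.120 CPM, and producer-cell levels were not analysed here. Carried RNA therefore cannot be told apart from expression by the treated cells. A general rise of silent genes was tested on 14 leukocyte and fibroblast markers, of which 1, COL6A3, was higher in every eVLP library. Together these 14 had 108 counts over the control and 144 over the eVLP libraries, a ratio per depth of 1.88 (95% counting interval 1.46 to 2.44), where the lower limits were 15.3 for NEFM and 11.6 for NEFL. A rise of all silent genes of that size is thus argued against by these sums. The bound of under 4 of 14 was met too, but only 5 of the 14 had over 9 counts over the eVLP libraries. A smaller rise is not excluded, since the interval of 1.46 to 2.44 lies above 1. Genes with a count numbered 27156 to 29018 in eVLP and 26251 to 27537 in control libraries. The 7SL RNA genes, whose RNA retroviral particles are known to pack, went apart: 1 of 2, RN7SL3, was higher in every eVLP library than in any other (10.7-fold, 5.05 ± 0.87 against 0.468 ± 0.146 CPM, adjusted p = 0.000153), whereas RN7SL2 fell (log2 change -1.02, 59.7 ± 19.8 against 121 ± 24.8 CPM, adjusted p = 0.0090), so packed RNA stays open for RN7SL3, whose reads its paralogs share. The libraries were enriched for mRNA on oligo(dT) beads, so these counts may depend on how much other RNA each preparation let through. Of 7 other small RNA genes of RNA polymerase III, which could have checked this, 0 were measured.

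The fall of ribosomal protein mRNAs in eVLP libraries had a median log2 change of -0.705 (SD over 24 members 0.197). GC content and gene length are argued against by a median of -0.629 with both trends removed, 23 members lower and camera adjusted p = 1.28e-27. Both were medians over the annotated transcripts of a gene, and only removal of a GC trend was tried on simulated data. Gene length is therefore argued against less firmly. Composition is argued against by medians of -0.713 with RLE scaling, -0.618 with upper-quartile scaling and -0.661 with the 1957 higher genes left out of the library sizes. A lower level of mRNAs with a 5' terminal oligopyrimidine tract as a class met the bound set for it. Of 20 non-ribosomal members 15 fell (16 adjusted over the list alone), such as EEF1B2 (-0.81) and TPT1 (-0.81). The 5 that did not pass included PABPC1 and EIF4B, at 0.14 and -0.04. This widens the pattern to most of that class and does not give its cause. Among 13 snoRNA host transcripts 5 fell (6 adjusted over the list alone), ZFAS1 most (-1.11), which is between the bounds set, and a biological cause in the delivery itself was not tested.

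HSPA6 was 314-fold higher in plasmid libraries. Reads of HSPA1A and HSPA1B assigned to HSPA6 are argued against by its fold being 95.4 times the larger of theirs. Sequence carried by the plasmids that matches HSPA6 could not be excluded: 11 of 13 heat shock genes rose with it, so a chaperone response was present, but no other fold of the list came near, and the plasmid sequences were not analysed here. The mock-transfected library stood at 2.02 CPM.

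Dividing the 6 libraries of a comparison into 3 and 3 gives 10 splits, too few for a share under 0.05. Of the 10, only 1, the real one, gave as many calls in each comparison: 1624, 4082 and 4736 genes, against 0 in every other split by edgeR, the only tool run on splits. At an unadjusted p under 0.05 the real splits gave 5118, 6696 and 7076 genes and the highest others 2586, 1681 and 919. For plasmid against eVLP, 4 splits part all 3 pairs, the highest other of which gave 232 at this unadjusted p, and the 6 that part 1 pair gave up to 919.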
